A study of Mus musculus with 33 samples.

How the data were processed

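Single ventricular cells were isolated by enzymatic digestion from mAG-hGem transgenic mouse hearts and sorted by green fluorescence, and cells positive for Tnnt2 and negative for Pdgfrb by PCR were sequenced, per the labels' protocols. Bases were called with CASAVA 1.8.2, reads were aligned to mm10 with STAR 2.4.0j and reads per gene were counted with HTSeq 0.6.1p1, per the submitters' processing notes. The settings of these steps, the handling of mates and any correction for duplicates were not given in the sources used here.

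The deposited table held a raw count for each of 20728 genes in 33 cells, and every column was used. Totals ran from 7.8 to 60.2 M counts per cell, 4941 genes had no count in any cell and 15787 had at least 1. No column was identical to another, no row carried a mitochondrially encoded gene and no row named anything other than a gene. The summed counts were 249.2 M for E14.5 positive, 318.4 M for E14.5 negative, 205.2 M for P19 positive and 126.6 M for P19 negative cells. Cells are numbered within each group in the order of their accessions.

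Each sample was 1 cell and no label named the animal, litter or date, so a group counted as 1 sample and no p-value, standard error or count of changed genes was computed. Counts were summed over the cells of a group and divided by the summed total, giving CPM of the sum, and 2 groups were compared as a log2 ratio in 4 comparisons. The 95% intervals for levels and ratios were exact Poisson and conditional binomial intervals, and those for shares of cells were exact Clopper-Pearson intervals. All of these cover counting error only, and reads copied by PCR are not independent molecules. From 1000 counts upward the upper Poisson bound lay at most 6.2% above the value. Where a group had 0 counts, the fold is a bound from a floor of 3 counts, given as "at least". Such a bound is on summed reads and not on the number of transcripts in the cells. The floor lies under the upper limit of the 95% interval for 0 counts, so such a fold is not the limit of that interval. With 1 to 3 counts the ratio is given with its interval. No ratio was formed where both groups were at or under the floor, a point settled after results had been seen.

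The 25 fixed lists held 520 genes, of which 514 were found, 5 of these by an older symbol. The 6 not found were Nup62, Cpt1b, Hba-a1, Hba-a2, Hbb-bt and Ahsp. The lists were S phase, G2/M, cytokinesis, cyclins with CDKs and E2F, cell cycle inhibitors, nuclear lamina, nuclear pore, nuclear transport, adult sarcomere, fetal programme, fatty acid oxidation, glycolysis, oxidative phosphorylation, ribosomal protein, adrenergic and ion channel, cardiomyocyte identity, atrial, fibroblast, endothelial, mural, macrophage, erythroid, epicardial, dissociation stress and apoptosis. A list was summarised by the median log2 ratio of members with at least 10 counts over both groups, with genes at 0 in a group taken at their bound. Its range came from 1000 Poisson redraws, and its percentile from 10000 random lists of the same size matched on level in 20 bins. Lists with fewer than 3 measured genes have no median. Percentiles are descriptions of these cells.

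Genes were named by a rule. It took Lmnb2, Lmnb1, Lmna, Gmnn, Ect2 and Mki67 in every comparison. It also took the 8 genes of largest ratio in each direction, ranked by the smallest ratio met when each cell was left out in turn. These needed at least 20 CPM in the higher group, a read in 3 of every 4 of its cells, the same direction in the median and mean over cells, and a symbol other than a predicted, clone, pseudogene or mitochondrial name. Of each list described it took up to 4 members, the 2 most abundant and those of largest ratio, and a member that the rule took is not reported here. The lists described, and genes named outside the rule (Tnni3 and Myh7 in a plot, and those in the last part), were chosen after values had been seen. Gene positions came from GENCODE vM21 on GRCm38.

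The groups, comparisons, lists, naming rule and first alternatives were set before the data were examined. These alternatives were the mean of CPM over cells, the difference of mean log2(CPM + 1), TMM factors from edgeR 4.0.16, size factors from DESeq2 1.42.0, thinning of every cell to 7.8 M counts, totals without the 10 most abundant genes of each group, a minimum of 100 or 1 counts, a floor of 1 count, detection at 5 counts and leaving out each cell. After the data had been seen 4 more were added: E14.5 cells with title numbers 1 to 10, those with 21 to 30, leaving out E14.5 negative cells 5 and 8, and leaving out P19 cells with at least 100 CPM of Fabp4. Sums, intervals and lists were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, factors with R 4.3.3 and plots with matplotlib 3.10.9.

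The calculation was tested on simulated data in which 200 genes were changed 2-fold or 4-fold. The true direction was found for 100% of them, the 95% intervals held the true value for 92.1% to 97.0%, a list of raised genes reached percentile 100, and unchanged lists had median percentiles of 38.7 to 61.7. The simulation held counting noise only and no variation between cells.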

Results

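Single ventricular cardiomyocytes were profiled by RNA sequencing from mice that carry the mAG-hGem reporter, a green fluorescent protein fused to part of geminin, which accumulates in the S, G2 and M phases and is degraded in G1. Cells came from embryonic day 14.5 (E14.5) and postnatal day 19 (P19) hearts and were sorted as reporter positive or reporter negative. The 33 cells comprised 10 E14.5 positive, 11 E14.5 negative, 8 P19 positive and 4 P19 negative cells. Total counts per cell ran from 11.9 to 60.2 M in E14.5 positive cells, from 7.8 to 55.0 M in E14.5 negative cells and from 13.2 to 40.1 M in P19 cells. The median number of genes with a read was 8703, 8104, 8722 and 8316. Each sample was 1 cell and no animal was named by the labels, so each group counted as 1 sample and no test was run. Differences are given as sizes, and intervals cover counting error only.

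The cells carried cardiomyocyte transcripts, but had been kept as Tnnt2 positive by PCR, so reads of that gene do not test their identity. Tnnt2, cardiac troponin T, had reads in every cell, with a median per cell of 3744 CPM in E14.5 positive cells, 4706 CPM in E14.5 negative cells, 6118 CPM in P19 positive cells and 8463 CPM in P19 negative cells. Pdgfrb, a mural and fibroblast receptor by which cells had been excluded with PCR, had 438 counts in P19 positive cell 8, 72 in E14.5 positive cell 9, 2 in P19 negative cell 1 and 0 in the other cells. E14.5 negative cell 5 held 60445 CPM of fibroblast genes beside 22482 CPM of cardiomyocyte identity genes. No other cell held more than 6422 CPM of the fibroblast list. Whether that sample was mixed was not tested, and it was kept in the sums of its group.

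The comparison of reporter positive with reporter negative cells at E14.5 asked how fetal cardiomyocytes sorted by the reporter differed. Negative cells were not free of S phase transcripts, at 482.4 to 20510 CPM of the list per cell against 1074 to 16967 CPM in positive cells. Genes of mitosis were higher by size in positive cells, although E14.5 negative cell 8, at 5094 CPM of G2/M genes, lay above the lowest positive cell, at 2569 CPM. Of the 46 G2/M genes, 45 were at least 2-fold higher in positive cells and none was as much lower, with a median log2 ratio of 4.13 (Poisson redraw interval 4.10 to 4.17). The list took 17314 CPM of the summed counts in positive cells and 1317 CPM in negative cells. Cdk1, the kinase that drives entry into mitosis, stood at 1971 CPM against 140.1 CPM, and Smc4, a condensin subunit, at 1650 CPM against 182.1 CPM. The spindle gene Hmmr was at 280.0 CPM in positive cells with 4 counts in the 11 negative cells (log2 ratio 14.44, 13.09 to 16.32), and the mitotic kinase Aurka was at 49.3 CPM with 1 count (13.94, 11.46 to 19.24).

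Cytokinesis genes followed, with 15 of 22 at least 2-fold higher, 1 as much lower and a median of 2.91. Anln, which encodes the contractile ring protein anillin, was higher by a log2 ratio of 7.27, Prc1, a protein of the central spindle, by 8.38 and Birc5, which encodes survivin, by 3.12, whereas the kinase Rock1 was at 331.7 CPM against 405.2 CPM. Ect2, the exchange factor that activates RhoA at the division plane, was at 530.1 CPM (527.3 to 533.0) in positive cells. In negative cells it was at 71.0 CPM (70.1 to 72.0), a log2 ratio of 2.90. E14.5 negative cells 5, 6 and 8 held 207.6, 217.1 and 265.4 CPM of Ect2, and no other negative cell held more than 0.1475 CPM. Mki67, the proliferation marker Ki-67, had reads in 10 of 10 positive cells (exact interval 69.2% to 100%) and in 3 of 11 negative cells (27.3%, 6.02% to 61.0%), at 700.3 CPM (697.0 to 703.6) against 35.1 CPM (34.5 to 35.8).

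Replication genes differed less. Of 32 S phase genes, 9 were at least 2-fold higher and 5 as much lower, with a median of 0.25, which was -0.04 without E14.5 positive cell 4. The sliding clamp gene Pcna was at 1580 CPM against 1362 CPM (0.21, or -0.14 without that cell). Much of its negative level lay in E14.5 negative cell 8, at 6949 CPM, with no other negative cell above 1045 CPM. The Pcna ratio is larger without E14.5 negative cell 8. The histone chaperone gene Nasp was at 685.3 CPM against 564.8 CPM. Rrm2, a ribonucleotide reductase subunit, was higher by 2.50 and the uracil glycosylase gene Ung lower, at -2.33. Among 26 cyclin, CDK and E2F genes the median was 0.57, with 11 at least 2-fold higher and 6 as much lower. Cyclin B1 (Ccnb1) was at 625.1 CPM against 0.195 CPM, cyclin A2 (Ccna2) was higher by 4.80 and E2f7 by 4.71. Gmnn, which encodes endogenous geminin, was at 142.7 CPM (141.2 to 144.1) against 105.4 CPM (104.3 to 106.5), a log2 ratio of 0.44.

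**Figure D1:**
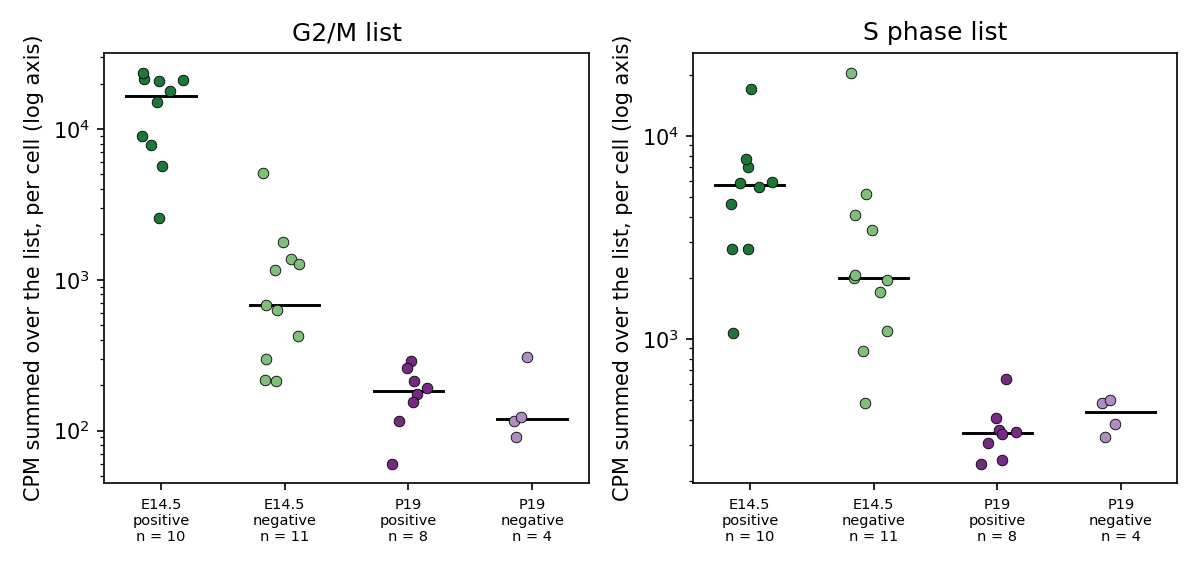
CPM summed over the G2/M list (left) and the S phase list (right) for each cell, on log axes, by group. Each point is 1 cell and each bar the median of its group. E14.5 positive cells lay between 2569 and 23658 CPM for the G2/M list, and P19 positive cells between 60.4 and 289.0 CPM.

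Some nuclear envelope genes were higher by size in E14.5 positive cells. Of 26 measured nuclear pore genes, 12 were at least 2-fold higher, 1 as much lower and 13 within 2-fold (median 0.75), among them Nup35 at 86.4 CPM against 10.3 CPM and Nup160 at 80.0 CPM against 10.6 CPM, while Seh1l was higher by 0.45 and Tpr lower, at -0.40. Of 17 nuclear lamina and inner membrane genes, 8 were at least 2-fold higher, 2 as much lower and 7 within 2-fold (median 0.63). Tmpo, which encodes lamina-associated polypeptide isoforms, was at 1475 CPM against 691.7 CPM, and the linker genes Syne2, Sun2 and Sun1 were higher by 1.86, 2.29 and 0.63. Sun2 took the opposite sign, at -1.99, among cells with title numbers 1 to 10.

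Lmnb2, which encodes lamin B2 and lies on chromosome 10 at 80901203 to 80918245 of GRCm38, had reads in 10 of 10 E14.5 positive cells (69.2% to 100%) and in 4 of 11 negative cells (36.4%, 10.9% to 69.2%). Its summed level was 6.84 CPM (6.52 to 7.18) against 0.185 CPM (0.141 to 0.239), a log2 ratio of 5.21 (4.83 to 5.61). Positive cells ranged from 0.191 to 26.6 CPM. Lmnb1, which encodes lamin B1, was at 31.4 CPM (30.7 to 32.1) against 11.6 CPM (11.2 to 12.0), a log2 ratio of 1.44, or 0.67 without E14.5 positive cell 9. Lmna, the gene of the A-type lamins, had the opposite sign, with 8.41 CPM (8.06 to 8.78) against 18.8 CPM (18.4 to 19.3) and a log2 ratio of -1.16, or -0.44 without E14.5 negative cell 8.

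The genes that led by size in E14.5 positive cells were Hmmr, Kif2c (13.60), Ankle1 (13.40), Cenpe (12.59), Aurka, Prr11 (12.87), Depdc1a (12.31) and Ccnb1 (11.65), of which 5 belonged to the G2/M list. Kif2c, Ankle1, Prr11 and Depdc1a each had 2 counts in the 11 negative cells, with intervals of 11.74 to 16.64, 11.55 to 16.45, 11.01 to 15.91 and 10.45 to 15.35. Those lower by size were Reln (-9.49), Tsr1 (-7.12), Agbl1 (-6.84), Hspa1a (-5.77), Uty (-5.54), Coq10a (-4.68), Def8 (-4.58) and Eml2 (-4.45). Uty is Y-linked.

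Stress and immediate early genes were lower by size in positive cells, with 11 of 19 at least 2-fold lower, none as much higher and a median of -1.17. Fos was at 1172 CPM against 2700 CPM and Egr1 at 3661 CPM against 2625 CPM. The heat shock genes Hspa1a and Hspa1b, near-identical copies whose reads are not separated with certainty, were lower at -5.77 and -10.28. Of 16 measured fibroblast genes 11 were at least 2-fold lower, with a median of -8.32, but this rested on E14.5 negative cell 5, which held 60445 CPM of the list, and the median without that cell was 0.49. The periostin gene Postn was at 1.58 CPM against 4371 CPM, decorin (Dcn) at 0.0201 CPM against 88.9 CPM, Col1a2 at 0.0522 CPM against 127.8 CPM and vimentin (Vim) at 1887 CPM against 1930 CPM. Without E14.5 negative cell 8 the G2/M median was 7.27, the cytokinesis median 4.80, the S phase median 1.31 and the Mki67 log2 ratio 15.98 (14.44 to 18.26, from 3 counts). Without E14.5 negative cell 11, which held most Lmnb2 counts of its group, the Lmnb2 log2 ratio was 7.50.

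The comparison at P19 asked whether reporter positive cells after birth differed from negative ones as they had before birth. G2/M transcripts were scarce in both groups, at 173.7 CPM of the summed counts in positive and 145.5 CPM in negative cells. Of 46 genes, 21 had enough counts, with 13 at least 2-fold higher in positive cells, 3 as much lower and a median of 1.69 (1.45 to 2.58). The centromere genes Cenpf and Cenpa, the most abundant of the list, stood at 76.7 CPM against 48.2 CPM (log2 ratio 0.67, or -0.08 without P19 positive cell 6) and at 38.5 CPM against 75.8 CPM. Ect2 had no read in any of the 12 cells, with upper counting limits of 0.0180 CPM in positive and 0.0292 CPM in negative cells. Mki67 had 224 counts, all in P19 positive cell 8, against 4 in P19 negative cell 1, a log2 ratio of 5.11. Without P19 positive cell 8 no count was left in positive cells, against 4 in negative cells. The log2 ratio from the floor was then -0.80, with an interval up to 0.22 that included no difference, so no direction is given. That cell also held 438 Pdgfrb counts, Col1a2 at 12.6 CPM, Cdh5 at 68.1 CPM and Fabp4 at 391.6 CPM. The G2/M median was 0.40 without P19 positive cell 8, 5.08 without P19 negative cell 1 and 4.74 without P19 negative cell 4.

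S phase genes went both ways at P19, with 8 of 22 measured genes at least 2-fold lower in positive cells, 5 as much higher, 9 within 2-fold and a median of -0.58, which was 0.18 without P19 negative cell 1. Ung was at 102.3 CPM against 161.9 CPM, Pcna at 69.0 CPM against 97.8 CPM, Tipin lower at -2.73 and Usp1 higher by 2.48. Gmnn was at 32.1 CPM (31.4 to 32.9) in positive and 56.2 CPM (54.9 to 57.5) in negative cells, a log2 ratio of -0.81. Lmnb2 had reads in 2 of 8 positive cells (25%, 3.19% to 65.1%) and 1 of 4 negative cells (25%, 0.631% to 80.6%), at 0.385 CPM (0.305 to 0.480) against 0.458 CPM (0.348 to 0.593). Its log2 ratio of -0.25 (-0.76 to 0.26) included 0 and was -6.28 (-11.60 to -3.74, from 1 count) without P19 positive cell 3. Without P19 negative cell 1 no count was left in negative cells, and Lmnb2 was at least 11.1-fold higher in positive cells. Lmnb1 was at 1.03 CPM (0.899 to 1.18) against 0 counts, at least 43.6-fold higher, with a bound on the log2 ratio of 3.76 without P19 positive cell 6, and Lmna was at 26.6 CPM (25.9 to 27.3) against 58.9 CPM (57.6 to 60.3), a log2 ratio of -1.15.

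Contractile, fatty acid oxidation and oxidative phosphorylation genes were close between the P19 groups. The adult sarcomere list had a median of -0.08 with 1 of 30 genes at least 2-fold lower and none as much higher. The ventricular light chain gene Myl3 was at 26203 CPM against 30329 CPM, the calcium pump gene Atp2a2 at 15946 CPM against 16630 CPM, Myh6 at 9700 CPM against 16069 CPM and Tcap at 279.2 CPM against 590.8 CPM. No measured gene of the fatty acid oxidation or oxidative phosphorylation lists differed by 2-fold. Of 17 measured glycolysis genes 2 were at least 2-fold lower in positive cells, none was as much higher and 15 were within 2-fold, with a median of -0.34, at percentile 0.5 of random lists (-0.47 to -0.20 when each cell was left out).

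The genes that led by size in P19 positive cells were Rhd (10.83, with 2 counts in negative cells and an interval of 8.98 to 13.88), Zfp667 (at least 895.5-fold), Bag4 (at least 845.9-fold), Fmnl2 (7.73), Bbs9 (7.31), Tmem183a (7.14), Zmat1 (7.06) and Sgpl1 (7.01). Those lower by size were Epb4.1l5 (-7.67), Zfp52 (-6.00), Fam123b (-5.99), Cspg4 (-5.44), Rps29 (-5.09), Adam22 (-4.36), Dhx33 (-4.25) and Fggy (-4.24). None of these 16 genes belonged to the G2/M or S phase list.

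Endothelial transcripts were present in both P19 groups, at 499.4 CPM of the summed counts in positive and 379.1 CPM in negative cells. Fabp4, a lipid carrier of capillary endothelium, was at 357.0 CPM against 298.1 CPM and Cav1 at 39.0 CPM against 31.9 CPM, with log2 ratios that took the opposite sign, -0.30 without P19 positive cell 4 and -0.41 without P19 positive cell 5. The junction gene Cdh5 was higher in positive cells by 3.26 and the VEGF receptor gene Kdr by 2.44. All Fabp4 counts of the negative group lay in P19 negative cell 1. Of 14 measured genes 7 were at least 2-fold higher in positive cells and 1 as much lower, with a median of 0.74 that was 6.70 without that cell.

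The comparison of P19 positive with E14.5 positive cells asked how cells sorted by the same reporter differed with age. All 46 G2/M genes were at least 2-fold lower in P19 positive cells, with a median of -11.64 (-11.66 to -11.21) in which 21 genes without a count in P19 positive cells stood at their bound. Cdk1 was at 1971 CPM in E14.5 positive cells and without a count in the 8 P19 cells, at least 134804-fold lower. Such bounds are on summed reads and not on transcripts, and whether a gene was read differed between cells of a group. Gmnn, for example, was at 0 CPM in P19 positive cell 5 and 66.8 CPM in P19 positive cell 2. Ube2c, which encodes an enzyme of the anaphase-promoting pathway, was at least 113411-fold lower and topoisomerase II alpha (Top2a) at least 58297-fold lower. Smc4 was at 18.4 CPM against 1650 CPM.

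Other cycle genes were lower too. Of 22 cytokinesis genes 17 were at least 2-fold lower and 1 as much higher. Their median was -10.12, or -11.66 without P19 positive cell 8. Among the lower ones were Ect2, at least 36252-fold lower, and Cdca8, at least 41492-fold lower. Birc5 was at -9.54 and Anln, with 2 counts at P19, at -16.18 (-19.23 to -14.33). Of 32 S phase genes 29 were at least 2-fold lower and 1 as much higher (median -6.10). Pcna was at 69.0 CPM against 1580 CPM, Nasp at 25.6 CPM against 685.3 CPM and Prim1, a primase subunit, at least 5253-fold lower. Mki67 was lower at -9.33, or at least 38530-fold lower without P19 positive cell 8, which held all of its counts, and Gmnn at -2.15, 32.1 CPM against 142.7 CPM.

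Lmnb2 was at 0.385 CPM in P19 positive and 6.84 CPM in E14.5 positive cells, a log2 ratio of -4.15 (-4.50 to -3.83). Of its 79 counts at P19, all but 1 lay in P19 positive cell 3, and the ratio without that cell was -10.18 (-15.48 to -7.70). Lmnb1 was lower at -4.93 and Lmna higher by 1.66. Most P19 Lmnb1 counts lay in P19 positive cell 6, at 4.22 CPM. The highest E14.5 Lmna level, 27.4 CPM, lay in E14.5 positive cell 10. Each of these ratios is larger in size without the cell named. The nuclear lamina genes had a median of -0.64, at percentile 55.1 of random lists matched on level, or -1.25 without P19 positive cell 6. The list as a whole held 406.5 CPM against 2235 CPM. Of 26 measured nuclear pore genes 21 were at least 2-fold lower and none as much higher (median -2.33), among them Nup155 at 2.37 CPM against 127.8 CPM, Nup37 at 5.51 CPM against 140.8 CPM and Seh1l at 45.3 CPM against 312.9 CPM. Tpr was at 122.8 CPM against 157.4 CPM and took the opposite sign with TMM factors (0.19) and with DESeq2 size factors (0.11).

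**Figure D2:**
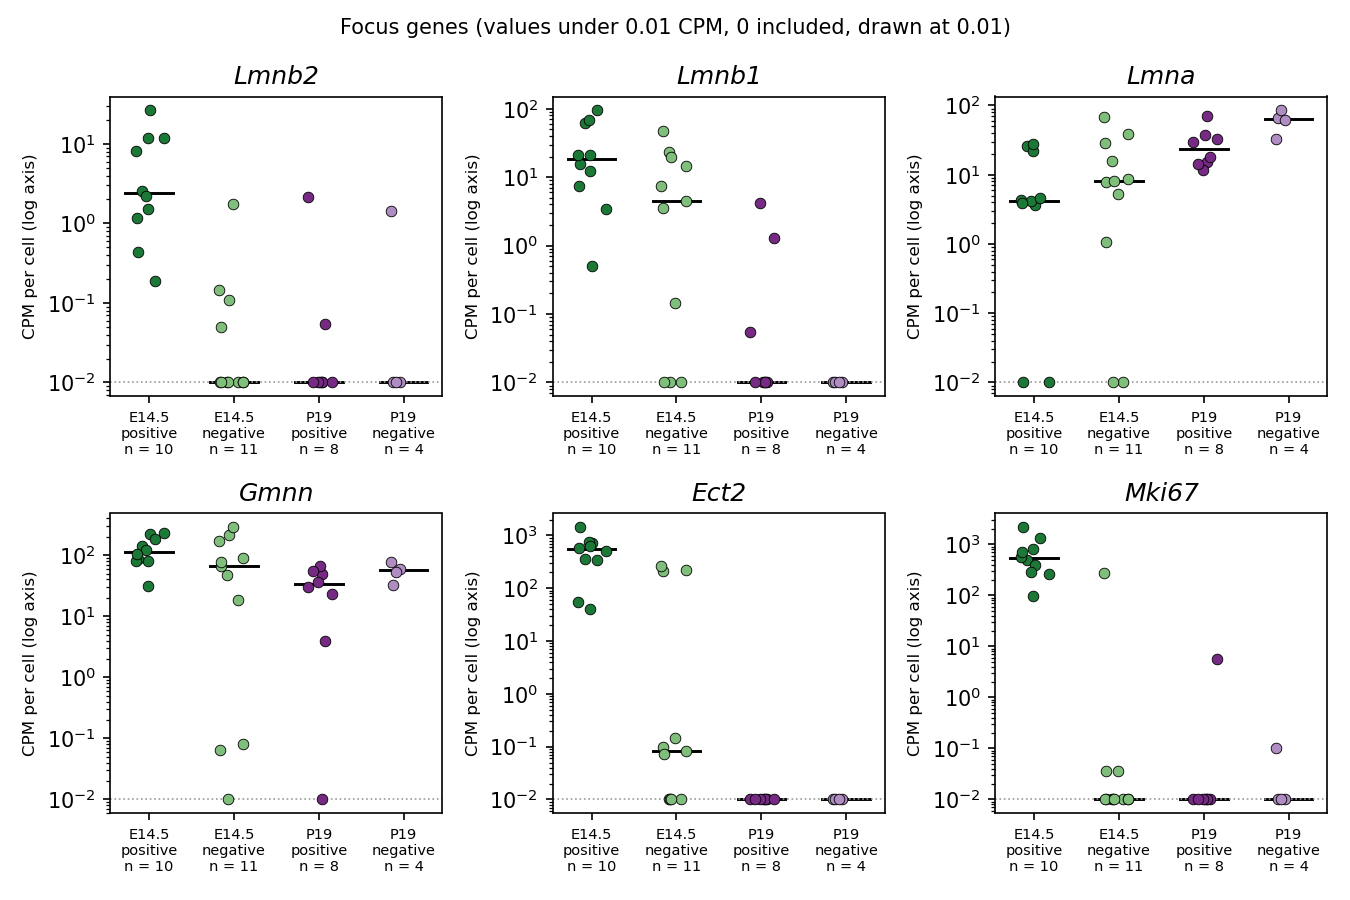
CPM per cell of Lmnb2, Lmnb1, Lmna, Gmnn, Ect2 and Mki67 by group, on log axes, with values under 0.01 CPM drawn at 0.01. Each point is 1 cell and each bar the median of its group. Ect2 had no read in any P19 cell, and Lmnb2 had reads in 10 of 10 E14.5 positive cells and 2 of 8 P19 positive cells.

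Contractile and fatty acid genes were higher by size at P19. Of 30 adult sarcomere genes 20 were at least 2-fold higher and 2 as much lower (median 2.21), among them Myl3 at 26203 CPM against 2052 CPM, Atp2a2 at 15946 CPM against 1854 CPM, the mitochondrial creatine kinase gene Ckmt2 at 5658 CPM with a log2 ratio of 8.30 and Myom2, an M-band protein gene, at 155.8 CPM against 0.0321 CPM. Of 25 measured fatty acid oxidation genes 22 were at least 2-fold higher and none as much lower (median 2.21), with lipoprotein lipase (Lpl) at 11735 CPM against 691.1 CPM, Fabp3 at 9454 CPM against 639.8 CPM, Ech1 at 1389 CPM against 37.8 CPM and Acadvl at 469.3 CPM with a log2 ratio of 4.48. Fetal programme genes went the other way, with 14 of 18 measured genes at least 2-fold lower and 1 as much higher. Their median was -6.53, or -5.45 without E14.5 positive cell 8. The imprinted RNA H19 was at least 14470-fold lower, the atrial light chain gene Myl7 at least 12319-fold lower and Mest at -9.75, whereas Acta2 was at 681.6 CPM against 511.1 CPM. Stress and immediate early genes were also lower at P19, 15 of 19 by at least 2-fold with 1 as much higher (median -2.49).

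The genes that led by size in P19 positive cells were Fabp4 (at least 29649-fold), Art1 (at least 29249-fold), Ces1d (at least 15068-fold), Trim54 (at least 8654-fold), Tuba8 (at least 6657-fold), Tmem100 (at least 6485-fold), Rxrg (at least 6134-fold) and Pla2g5 (14.52, with 2 counts at E14.5 and an interval of 12.67 to 17.57). Those lower by size were Cdk1, Bex4 (at least 123099-fold), Ube2c, Bex1 (at least 60809-fold), Top2a, Trim59 (at least 55756-fold), Anln and Spc25 (-15.78). Of 15 endothelial genes 12 were at least 2-fold higher and 2 as much lower at P19 (median 5.50), with Kdr at least 2597-fold higher, Cdh5 higher by 10.43 and Cav1 by 6.57. Without the P19 cells that held at least 100 CPM of Fabp4, that median was -1.74 and the G2/M median -11.78.

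The comparison of P19 negative with E14.5 negative cells asked how reporter negative cardiomyocytes differed with age. Adult sarcomere genes were higher by size at P19, 19 of 30 by at least 2-fold with 1 as much lower and a median of 2.58 (2.57 to 2.59). Myl3 was at 30329 CPM against 1959 CPM, Atp2a2 at 16630 CPM against 2898 CPM, Ckmt2 at 6586 CPM against 56.1 CPM and Myom2 at 98.1 CPM against 0.0126 CPM. Of 25 measured fatty acid oxidation genes 19 were at least 2-fold higher and 1 as much lower (median 1.75, 1.73 to 1.76), with Lpl at 10586 CPM against 996.1 CPM, Fabp3 at 8691 CPM against 527.2 CPM, Ech1 at 1618 CPM against 52.1 CPM and Acadvl at 693.6 CPM against 53.9 CPM. Oxidative phosphorylation genes were higher by size with a median of 1.18, 15 of 27 by at least 2-fold and none as much lower. Uqcrc1 was higher by 4.22 and Cox4i1 by 3.61, Atp5g3 was at 34275 CPM against 15135 CPM and Atp5a1 at 10702 CPM against 5982 CPM.

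**Figure D3:**
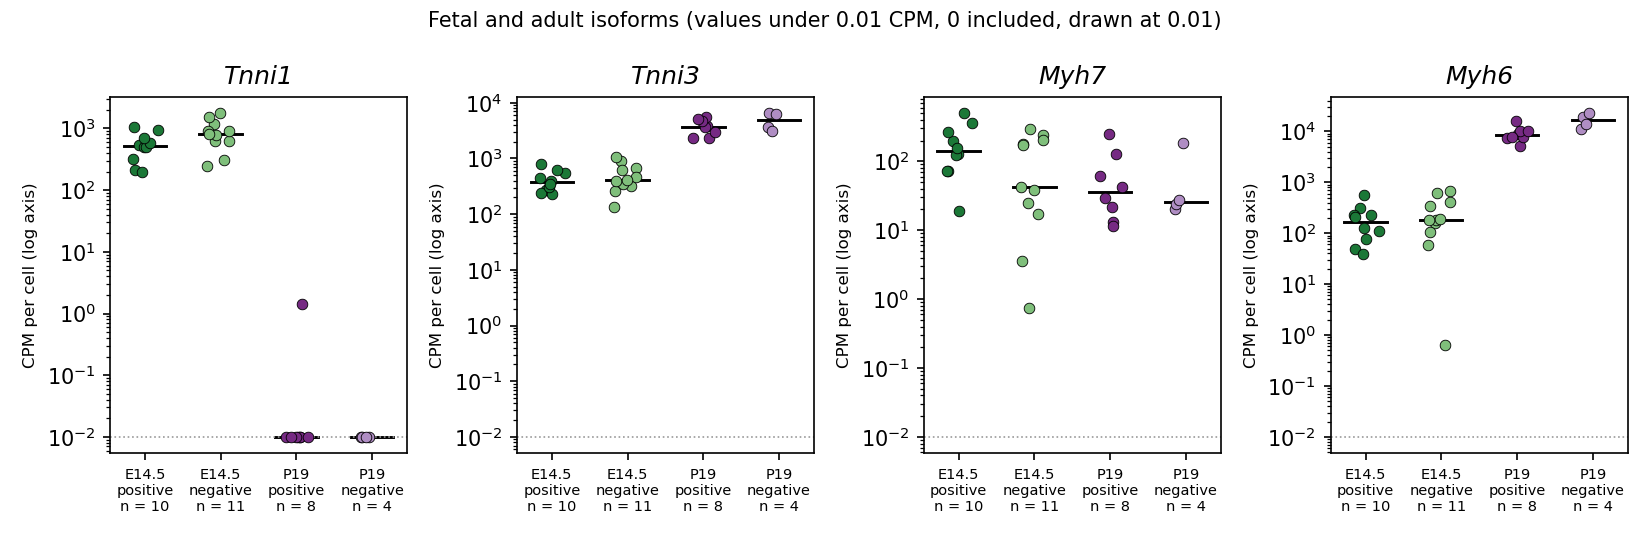
CPM per cell of the troponin I genes Tnni1 and Tnni3 and the myosin heavy chain genes Myh7 and Myh6 by group, on log axes, with values under 0.01 CPM drawn at 0.01. Each point is 1 cell and each bar the median of its group. Tnni1 lay between 197.8 and 1798 CPM in E14.5 cells and at or under 1.41 CPM in P19 cells, while Myh6 lay at or under 678.9 CPM at E14.5 and between 5067 and 23210 CPM at P19.

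The fetal programme was lower by size at P19, with 16 of 18 measured genes at least 2-fold lower, 1 as much higher and a median of -7.22. Tnni1, the fetal troponin I gene, was at 869.9 CPM in E14.5 negative cells and had no count in the 4 P19 negative cells, at least 36695-fold lower. The growth factor gene Igf2 was at least 17996-fold lower and H19 at least 8999-fold lower, while Acta2 was at 793.9 CPM against 447.0 CPM. Stress and immediate early genes were lower as well, 18 of 19 by at least 2-fold with 1 as much higher (median -5.86). Fos was at 41.7 CPM against 2700 CPM, Egr1 at 45.3 CPM against 2625 CPM, Atf3 at least 30057-fold lower and Hspa1a at least 14832-fold lower. Both groups had been dissociated enzymatically and sorted.

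S phase genes were lower by size in P19 negative cells, 29 of 32 by at least 2-fold with none as much higher and a median of -5.82, which was -3.90 without E14.5 negative cell 8. Pcna was at 97.8 CPM against 1362 CPM and the helicase gene Mcm4 at 2.17 CPM against 726.9 CPM, while Mcm6 was at least 14871-fold lower and Rrm2 at least 4424-fold lower. Gmnn was lower at -0.91 and Ect2 at least 2997-fold lower. Gmnn took the opposite sign, 1.00, as a difference of mean log2(CPM + 1) over cells. Mki67 was lower at -10.12 (-11.99 to -8.76) and took the opposite sign, 1.55 (-1.02 to 4.32, from 4 and 3 counts), without E14.5 negative cell 8. Lmnb1 was at least 489.3-fold lower at P19 and Lmna higher by 1.65. E14.5 negative cell 8 held the highest Lmna level of its group, 69.1 CPM, and the Lmna ratio is larger without it. Lmnb2, with 58 and 59 counts, was at 0.458 CPM against 0.185 CPM (log2 ratio 1.31, 0.76 to 1.85) and took the opposite sign, at least 5.34-fold lower, without P19 negative cell 1, which held all P19 counts.

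The genes that led by size in P19 negative cells were Rpl3l (at least 56103-fold), a ribosomal protein gene of striated muscle, Ces1d (at least 30968-fold), Xirp2 (at least 28816-fold), Plin5 (at least 18832-fold), Rxrg (at least 10298-fold), Fbp2 (15.20, with 1 count at E14.5 and an interval of 12.72 to 20.50), Mylk4 (14.43, with 2 counts and an interval of 12.58 to 17.47) and Trim54 (13.66). Those lower by size were Vim (at least 81403-fold), Fstl1 (at least 60182-fold), Tnni1, Atf3, Bex4 (at least 28345-fold), Bex1 (at least 24764-fold), Ndn (at least 23217-fold) and Id2, with 2 counts at P19 and a log2 ratio of -15.72 (-18.76 to -13.87).

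The median log2 ratio of all measured genes was -0.12 for positive against negative at E14.5, 0.16 at P19, -0.77 for P19 positive against E14.5 positive and -1.07 for P19 negative against E14.5 negative. The 10 most abundant genes held a median of 23.5% of counts in P19 positive and 24.9% in P19 negative cells, against 9.57% and 10.2% at E14.5. Other scalings moved the all-gene median by up to 0.76 between ages. The difference of mean log2(CPM + 1), which keeps the totals, moved it by up to 0.95. Age ratios are therefore best read relative to these medians.

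**Figure D4:**
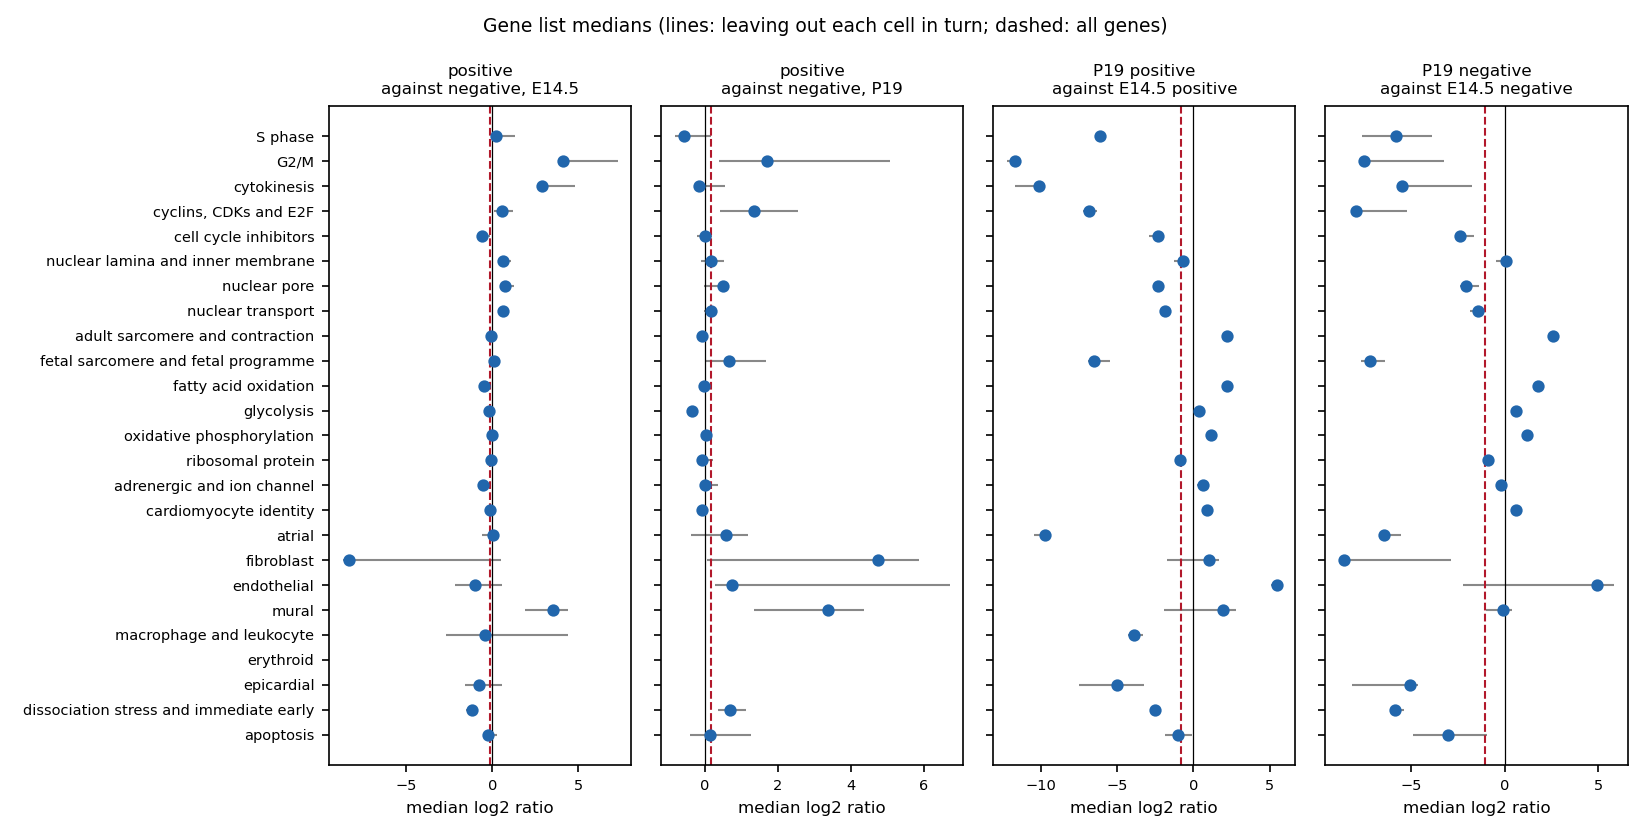
Median log2 ratio of each gene list (points) in the 4 comparisons, with lines from the lowest to the highest median when each cell was left out in turn. The dashed line is the median of all measured genes, and lists with fewer than 3 measured genes have no point. The G2/M list stood at 4.13 for positive against negative at E14.5 and at -11.64 for P19 positive against E14.5 positive.

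Set side by side, the positive against negative log2 ratio was lower at P19 than at E14.5 by size for some cycle measures and higher for others, and these differences were not tested. The G2/M median was 1.69 at P19 and 4.13 at E14.5, a difference of -2.44, but the P19 median was 5.08 without P19 negative cell 1. The cytokinesis median was -0.17 at P19, or 0.56 without that cell, and 2.91 at E14.5, a difference of -3.08. The cyclin, CDK and E2F median was 1.35 at P19, or 0.42 without P19 positive cell 4, and 0.57 at E14.5, or 1.22 without E14.5 negative cell 8, and the list as a whole held 180.6 CPM in P19 positive and 181.7 CPM in P19 negative cells. Mki67 was at 5.11 and 4.32, and this order rested on P19 positive cell 8 and on E14.5 negative cell 8. Without the former the P19 ratio was -0.80 from the floor, with a counting interval that included no difference. Without the latter the E14.5 ratio was 15.98. Lmnb1 had a bound of 5.45 at P19 and a ratio of 1.44 at E14.5. Lmnb2 was at 5.21 at E14.5, or 7.50 without E14.5 negative cell 11, and at -0.25 at P19, where its sign rested on single cells, with -6.28 (-11.60 to -3.74, from 1 count) without P19 positive cell 3 and a bound of 3.47 without P19 negative cell 1. Lmna was lower in positive cells at both ages, at -1.16, or -0.44 without E14.5 negative cell 8, and at -1.15, and the adult sarcomere medians were -0.04 and -0.08.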

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

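All tests of explanations in this part were chosen only after the results had been seen. In the groups of 4 to 10 cells, 16 measures per group were searched for a cell far from the others of its group, which gave 48 sets of values. The cutoffs would mark about 1 set in 20, or 2.4 of 48, if values were normally distributed, and 7 were found. The values were CPM without logs and some lists shared genes, so 7 cannot be set against a rate expected by chance. Each of the 7 was the highest value of its group. The group of 11 cells was not examined in this way.

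E14.5 positive cell 4 held 16967 CPM of S phase genes, with the next cell at 7660 CPM. E14.5 positive cell 8 held 99.8 CPM of endothelial genes, next to 52.0 CPM, and E14.5 positive cell 1 held 29856 CPM of stress and immediate early genes, next to 12683 CPM. P19 positive cell 4 stood apart for S phase genes, 638.4 CPM next to 409.5 CPM, and for nuclear pore genes, 849.5 CPM next to 556.8 CPM. P19 negative cell 3 held 305.7 CPM of G2/M genes, next to 122.7 CPM, and P19 negative cell 1 held 1197 CPM of endothelial genes, next to 1.09 CPM.

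G2/M transcripts were almost absent from P19 positive cells. Lower detection of all genes of that level was argued against, since random lists matched on level had a median log2 ratio of -0.66 where the G2/M list had -11.64. For a halt in S phase before G2/M transcripts appear, S phase levels were compared between ages. The highest of a P19 positive cell, 638.4 CPM in cell 4, lay under the lowest of an E14.5 positive cell, 1074 CPM. That lowest cell had a ratio of S phase to G2/M counts of only 0.05. The gap is no larger than the all-gene shift between these groups, a median log2 ratio of -0.77, so it cannot decide for P19 positive cell 4. The other P19 positive cells, at 409.5 CPM or less, lay further below, which argues against such a halt in them. A gate that took P19 cells without reporter stays open, because the table carried 0 rows for the reporter itself. Endogenous Gmnn, at -0.81 in P19 positive against negative cells, cannot decide this. At E14.5 it was at 0.44 where the G2/M median was 4.13. A difference with age in how the reporter relates to the cycle also stays open and was not tested, and age cannot be told apart from any difference in batch.

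E14.5 negative cell 8 held cell cycle transcripts near the level of positive cells. A swap with one of the E14.5 positive cells was argued against, since the lowest G2/M level of a positive cell, 2569 CPM, lay above the highest of the other negative cells, 1776 CPM. Admixed RNA of a positive cell stays open. The S phase level of cell 8, 20510 CPM, was above the highest of the 10 measured positive cells, 16967 CPM. Those cells ran from 1074 CPM upward, and so few cells do not limit what a further positive cell could hold. A position earlier in the cycle stays open, because its ratio of S phase to G2/M counts, 4.03, was above the highest positive cell, 2.99, but lay within the other negative cells, 0.76 to 9.16. A single wrong label or a swap with a cell outside this series stays open.

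Endothelial transcripts were high in some P19 cells and near 0 in others. The list ran from 0 counts in P19 negative cell 3, at a floor of 0.128 CPM, to 1971 CPM. Free RNA shared alike by all P19 cells would not give this range. The range restates the pattern, so it was no separate test of that explanation. In the 6 P19 cells with at least 100 CPM of Fabp4, 4 to 11 of the 14 other list members reached 1 CPM, and in the other 6 cells 0 did. That 0 depends on the cutoff, since P19 positive cell 3, among the other cells, held Cdh5 at 0.9962 CPM. The large difference between the cells is what endothelial material attached to some of them would give. Expression by those cardiomyocytes stays open and was not tested.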

How the results depend on the processing

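The 2 alternatives by title number, the one without E14.5 negative cells 5 and 8 and the one without Fabp4-high P19 cells were chosen only after results had been seen. Of 88 list medians 8 changed sign from a size of at least 2-fold under some alternative, and of 175 gene ratios 10 did, with 18 values each. The 88 and 175 include medians and ratios under 2-fold, whose changes of sign were not counted, so these shares understate how often signs changed. TMM factors, DESeq2 size factors, the mean of CPM, thinning, totals without abundant genes and the floor of 1 count turned none of those of at least 2-fold. The cause was not tested except where the cells left out show it. No paired analysis was possible because title numbers shared between groups only name cells. The table held no mitochondrially encoded gene, so that part of an alternative had nothing to remove.

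Scaling, and the use of mean log2 in place of sums, shifted the all-gene median. At E14.5 the shift was 0.13 with TMM, 0.14 with DESeq2 and 0.25 with mean log2(CPM + 1), and at P19 it was -0.15 with DESeq2 and -0.12 with mean log2. For positive cells between ages it was 0.55, 0.47 and 0.56 with TMM, DESeq2 and mean log2 and 0.32 without abundant genes. For negative cells it was 0.72, 0.76, 0.95 and 0.36 in the same order.

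The G2/M median at E14.5, 4.13, was 5.25 with mean log2, 4.26 with TMM, 4.27 with DESeq2, 7.20 with title numbers 1 to 10, 4.07 with 21 to 30, 7.12 without E14.5 negative cells 5 and 8, and 3.88 to 7.27 when each cell was left out. At P19 the median of 1.69 was 1.45 with the mean of CPM, 0.15 with mean log2, 1.11 thinned, 1.13 without Fabp4-high cells, 5.11 from at least 100 counts, 0.49 from at least 1 count and 0.40 to 5.08 when each cell was left out. Between positive cells of both ages, -11.64 was -6.39 with mean log2, -11.09 with TMM, -11.17 with DESeq2, -10.00 thinned, -12.36 with a floor of 1 count, -10.83 and -12.00 with title numbers 1 to 10 and 21 to 30, -11.78 without Fabp4-high cells and -12.20 to -11.27 when each cell was left out.

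Lmnb2 between positive cells, -4.15, was -4.59 with the mean of CPM, -1.99 with mean log2, -3.60 with TMM, -3.68 with DESeq2, -4.82 thinned, -2.79 without Fabp4-high cells and -10.18 to -3.76 when each cell was left out. Detection from 5 counts gave Lmnb2 in 10, 2, 1 and 1 cells of the E14.5 positive, E14.5 negative, P19 positive and P19 negative groups. The adult sarcomere median between negative cells, 2.58, was 2.38 with the mean of CPM, 3.30 with TMM, 3.34 with DESeq2, 2.38 thinned, 2.93 without abundant genes, 2.11 and 2.74 with title numbers 1 to 10 and 21 to 30, 2.4 without E14.5 negative cells 5 and 8, 2.60 without Fabp4-high cells and 2.44 to 2.65 when each cell was left out. The fatty acid oxidation median, 1.75, was 1.86, 2.50, 2.47, 2.51, 1.86 and 2.10 with the mean of CPM, mean log2, TMM, DESeq2, thinning and without abundant genes, 1.94 and 1.84 with title numbers 1 to 10 and 21 to 30, 1.61 without cells 5 and 8, and 1.55 to 1.99 when each cell was left out.

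At E14.5 the endothelial median of -1.01 turned to 0.04 with mean log2, 0.82 with title numbers 1 to 10, 0.23 with 21 to 30, 0.81 without E14.5 negative cells 5 and 8, 0.21 from at least 100 counts, 0.49 from at least 1 count and 0.56 without E14.5 negative cell 4. Title numbers 21 to 30 turned the mural median to -0.31, Col1a2 to 1.20, Dcn to 0.82 and Postn to 1.08, and title numbers 1 to 10 turned Sun2 to -1.99. Without E14.5 negative cells 5 and 8 the fibroblast median was 0.61, Col1a2 0.69, Dcn 0.31, Postn 0.58 and, between negative cells of both ages, Mki67 1.38 (-1.18 to 4.15, from 4 and 3 counts). Without cell 5 alone the fibroblast median was 0.49, Col1a2 0.91, Dcn 0.53 and Postn 0.79, and without cell 8 alone Mki67 was 1.55. Leaving out each cell gave ranges of -8.66 to 0.49 for the fibroblast median, -2.16 to 0.56 for the endothelial median, -12.69 to 0.91 for Col1a2, -14.17 to 0.53 for Dcn, -12.43 to 0.79 for Postn and -10.39 to 1.55 for Mki67 between negative cells.

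Leaving out Fabp4-high P19 cells, a choice that is circular for the endothelial list, turned the P19 fibroblast median to -1.01, Fmnl2 to -2.77 (-5.94 to -0.67, from 2 counts) and Kdr to -2.33. Between positive cells it turned the fibroblast, endothelial and mural medians to -3.08, -1.74 and -4.04 and Cav1 to -1.69. Between negative cells, where it removes P19 negative cell 1, the endothelial median was -2.25 and Lmnb2 a bound of -2.42 with no P19 count left, as in leaving out that cell alone. Leaving out each cell gave -2.25 to 5.83 and -2.42 to 3.6 for these. Without P19 positive cell 8 Mki67 at P19 was -0.80 from the floor (up to 5.40 over the other cells). No positive count was left, and the counting interval included no difference. Between positive cells, without P19 positive cell 8, the fibroblast median was -1.69 (up to 1.71) and the mural median -1.90 (up to 2.81).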

Other observations

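Genes named in this part were chosen after their values had been seen. Of 21 nuclear transport genes, 7 were at least 2-fold higher in positive cells at E14.5, 4 as much lower and 10 within 2-fold, with a median of 0.61. Between ages, 13 were at least 2-fold lower at P19 in positive cells (median -1.82) and 12 in negative cells (median -1.44). Ran, the GTPase that sets the direction of transport, was at 2796 CPM in E14.5 positive, 1419 CPM in E14.5 negative, 416.6 CPM in P19 positive and 344.9 CPM in P19 negative cells, and the exportin gene Xpo1 at 898.1, 329.6, 104.1 and 30.3 CPM. Cell cycle inhibitors had medians of -0.58 at E14.5, and -2.32 and -2.42 between ages in positive and negative cells, while the list as a whole held 1438, 2468, 1154 and 1022 CPM in the order given for Ran. Cdkn1c, which encodes p57, was at 262.0 CPM in E14.5 positive and 639.2 CPM in E14.5 negative cells and at 17.4 and 6.06 CPM at P19. Nuclear pore medians were 0.51 at P19 and -2.07 between negative cells, and lamina medians 0.18 and 0.05, while the lamina list as a whole held 364.5 CPM in P19 negative and 1148 CPM in E14.5 negative cells. Of these, 0.51 was -0.02 without P19 positive cell 2, 0.18 was -0.11 without P19 negative cell 2 and 0.05 was -0.48 without P19 negative cell 1.

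Glycolysis genes had medians of -0.20 at E14.5, -0.34 at P19, and 0.35 and 0.58 between ages, and the lactate dehydrogenase gene Ldhb was at 412.7, 548.8, 2461 and 2860 CPM in the order given for Ran. Ribosomal protein genes had medians of -0.05, -0.09, -0.89 and -0.90, the last 2 near the all-gene medians, and Rpl4 was at 9849, 6703, 978.1 and 841.9 CPM. Fatty acid oxidation genes had a median of -0.46 at E14.5, and oxidative phosphorylation genes 0.02 at P19 and 1.16 between positive cells. Adrenergic and ion channel genes had medians of -0.51 at E14.5, 0.62 between positive and -0.20 between negative cells, while the list as a whole held 8917 CPM in E14.5 positive, 10757 CPM in E14.5 negative, 4039 CPM in P19 positive and 3842 CPM in P19 negative cells. The exchanger gene Slc8a1 was at 3633, 4267, 564.6 and 372.7 CPM. Cardiomyocyte identity genes had medians of -0.10, -0.09, 0.87 and 0.59, with the cardiac actin gene Actc1 at 9021, 7608, 15877 and 16391 CPM. Atrial genes had medians of 0.03, 0.59, -9.69 and -6.45, with the light chain gene Myl4 at 507.6, 774.0, 1.26 and 0.284 CPM. Apoptosis genes had medians of -0.23, 0.13, -0.99 and -3.02, the last being -0.95 without E14.5 negative cell 11 and -4.94 without P19 negative cell 1, with 463.6 CPM in P19 negative and 540.5 CPM in E14.5 negative cells for the list as a whole, and Mcl1, which encodes a survival factor, was at 323.7, 292.5, 306.5 and 283.2 CPM. The P19 atrial median was -0.37 without P19 positive cell 7, and that list as a whole held 25.6 CPM in positive and 52.5 CPM in negative cells. The P19 apoptosis median was -0.40 without P19 positive cell 6 and 1.26 without P19 negative cell 4, the one between positive cells was -1.87 without P19 positive cell 5 and -0.07 without E14.5 positive cell 9, the E14.5 apoptosis median was 0.28 without E14.5 negative cell 8 and the P19 ribosomal median 0.23 without P19 negative cell 1. The E14.5 atrial, ribosomal and identity medians and the P19 oxidative phosphorylation median also changed sign when 1 cell was left out (E14.5 positive cells 8 and 9, E14.5 negative cell 7 and P19 positive cell 5), to -0.56, 0.05, 0.05 and -0.04.

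Markers of other cell types were measured in the same cells. Mural genes had a median of 3.53 at E14.5, or -0.31 with title numbers 21 to 30, although the list as a whole was lower in positive cells, 178.0 CPM against 305.8 CPM. Their medians were 3.37 at P19, or 1.34 without P19 positive cell 8, 1.97 between positive cells, or -1.90 without that cell, and -0.10 between negative cells, or 0.36 without P19 negative cell 2, and Rgs5 had reads among P19 positive cells (10.3 CPM) and none in the other groups. Fibroblast medians were 4.73 at P19, or 0.06 without P19 positive cell 8, then 1.06 between positive cells, or -1.69 without P19 positive cell 8, although the list as a whole held 109.4 CPM in P19 positive and 2324 CPM in E14.5 positive cells. Between negative cells the median was -8.61, or -2.88 without E14.5 negative cell 5. The endothelial median was 4.92 between negative cells, or -2.25 without P19 negative cell 1. Macrophage genes had 3 measured members and a median of -0.42 at E14.5, or 4.41 without E14.5 negative cell 6, with Lyz2 at 3.48 CPM in positive and 24.1 CPM in negative cells, and none was measured between P19 groups. Erythroid genes had at most 2 measured members, and Alas2 was at 1.60, 4.30, 0.556 and 0.0316 CPM. Epicardial genes, with 5 measured members, had a median of -0.75 at E14.5, or 0.58 without E14.5 negative cell 8. Between ages the medians were -4.97 in positive and -5.09 in negative cells. Leaving out each cell gave -7.46 to -3.25 and -8.17 to -4.63 for these. Wt1 was at 7.09 CPM in E14.5 positive and 52.6 CPM in E14.5 negative cells and without a count at P19.

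Among counts from 1 to 9, the share that was even lay between 63.1% and 81.7% in E14.5 cells and between 85.4% and 93.0% in P19 cells, without overlap. Even counts thus exceeded odd ones in every cell, which single independent counts would not give. Intervals on counts, above all those from few counts, are too narrow if fragments were counted more than once.

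The E14.5 cells formed 2 runs of title numbers. Positive cells numbered 1 to 10 had 11.9 to 18.3 M counts and those numbered 21 to 30 had 27.4 to 60.2 M, with median G2/M levels of 8394 and 21029 CPM. In negative cells the totals were 7.8 to 30.5 and 24.8 to 55.0 M. The labels did not say what the runs stood for.

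Y-linked transcripts were low in the positive cells of the second run. All 4 positive cells numbered 21 to 30 had at most 9.83 CPM from 4 Y-linked genes, whereas 5 of the 6 numbered 1 to 10 had 235.5 to 1400 CPM and E14.5 positive cell 1 had 6.42 CPM. Negative cells numbered 21 to 30 were mixed, at 1335, 6.25, 721.2, 4.54, 37.5 and 3.69 CPM.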
